A study of Homo sapiens with 3 samples.

How the data were processed

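RNA of KYSE140, an established human oesophageal squamous cell carcinoma line, was measured on 3 Affymetrix oligonucleotide arrays. Per the labels' protocols, cells were grown in RPMI medium with serum, exposed to cisplatin at 10 mM for 12 h or left untreated, and lysed in Trizol, and biotin-labelled cRNA was made from total RNA with the manufacturer's in vitro transcription kit. The labels give 1 untreated array and 2 cisplatin arrays, titled B1 and B2. The concentration is given as the labels state it; cisplatin is usually applied to cultured cells at micromolar concentrations, so the labelled unit is in doubt. Nothing in the labels says whether B1 and B2 came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. P-values of gene lists and of gene order use genes as replicates, so they do not measure the spread between cultures.

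The deposited values are intensities, 1 per probe set, for 54675 probe sets on each array. Per the submitters' processing notes they were made with RMA, a method that corrects background, normalizes between arrays and summarises probes into probe sets. Its version, the chip definition and detection calls are not given in the sources used here. RMA ends on the log2 scale, whereas the deposited intensities ran from 3.03 to 19645 and had medians of 34.8 (untreated), 35.9 (B1) and 35.6 (B2), so they are on a linear scale. They were put back on the log2 scale before any test, with no pseudocount because every value was above 0. Values were not centred by gene. Because no detection calls were used, a dim probe set cannot be told from an undetected one, and the number of arrays limits the precision of every value.

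The 62 control probe sets were left out of the tests. Of the others, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several, and 11721 were not listed there and are unnamed here. Symbols were updated by gene number to the annotation of GRCh38.p14, in which 19735 of 19775 genes were found. Each gene was represented by its probe set with the highest mean log2 value over the 3 arrays. Genomic spans, the distance from the first to the last annotated base of a gene, came from the same annotation and were used without coordinates, since probe sets carry none.

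Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), cisplatin against untreated, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, from the cisplatin pair, and 2.01 prior degrees of freedom, and the lone untreated array was assumed to vary like the treated arrays. Beside the test, a size rule counted genes whose 2 cisplatin arrays both differed from the untreated array by at least 2-fold in the same direction. Shifts of 29 gene lists, written before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Of the 645 list entries, 577 were measured, after older symbols had been matched. Entries of a list that matched the same gene were counted once in its number of genes, so those numbers add to fewer. Each list's median was also ranked among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays and is not a test.

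The genes named were chosen by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest genes that pass both the test and the size rule, filled from genes meeting the size rule alone with a mean log2 value of at least 6, then up to 4 members of each list with the largest moderated t, 14 lead genes and 8 reference genes. As no gene passed the test, all 24 came from the size rule alone. TP63 was not measured by a probe set with 1 gene symbol. Genes outside the rule are marked where they appear. The level of 6 did not apply to list members and lead genes, and FOSB, HSPA6, H2BC21, EGLN3, COL5A1 and ATP7B were among those below it.

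The limma fit was tested on simulated data drawn from the 19775 genes' own means and from the fitted spread, with 200 genes changed in each of 10 simulations. It recovered 0% of genes changed by 1, 2, 3 or 4 on the log2 scale, and called 0.2 unchanged genes per simulation. Camera called a simulated shift of 0.5 in the immediate early list in 10 of 10 simulations and 0 of 270 unshifted lists. Genes were simulated independently of each other, so the 0 of 270 does not cover false calls from genes that vary together. Alternatives covered filters on dim genes, the variance prior, the choice of probe sets, quantile normalization, median centring, other size thresholds, other list tests and each cisplatin array alone. No columns of the table were left unused.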

Results

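Expression was measured in KYSE140 oesophageal squamous carcinoma cells left untreated (1 array) or exposed to cisplatin, a platinum drug that crosslinks DNA, at a labelled 10 mM for 12 h (2 arrays, B1 and B2). The comparison asked which transcripts differed after cisplatin. The untreated group had no replicate, so every value of it is that of a single array. Standard errors (SE) combine the spread of the cisplatin pair with a prior spread pooled over genes. They are therefore not a gene's own measured spread: for ID2 the SD between the cisplatin arrays was 0.037. After updating names, 19775 genes were compared. Log2 differences are cisplatin minus untreated.

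The 12 highest genes in both cisplatin arrays by the size rule included ID2, PMAIP1, CDKN1A, ATF3 and FOS. ID2, an inhibitor of basic helix-loop-helix transcription factors, had an intensity of 272 in the untreated array, 1609 in B1 and 1551 in B2, which is 5.80-fold higher on average (log2 difference 2.54, SE 0.19). PMAIP1 (NOXA), a pro-apoptotic BH3-only protein, went from 1013 to 3269 and 3568, or 3.37-fold (log2 1.75, SE 0.19). CDKN1A (p21), the cyclin-dependent kinase inhibitor, had log2 differences of 1.02 in B1 and 1.99 in B2. The stress factor ATF3 was higher by 1.91 and 1.55, FOS by 2.01 and 1.40, and the cell-cycle regulator SERTAD1 by 1.65 and 1.91. The small GTPase gene RHOB was higher by 1.44 and 1.88, although only 2 of its 5 probe sets were higher in both arrays. BAMBI, a pseudoreceptor of the TGF-beta family, differed by 1.30 and 1.99, the homeobox gene DLX2 by 1.22 and 1.91, the epithelial transcription factor OVOL1 by 1.43 and 1.64, the chemokine receptor CXCR4 by 1.06 and 2.21, and the membrane protein FLRT3 by 1.01 and 2.96. These values are from the brightest probe set. Over all probe sets of a gene the mean log2 difference was smaller for RHOB (0.45), DLX2 (0.80), OVOL1 (1.01), CXCR4 (1.16) and ATF3 (1.19). In the untreated array FOS (intensity 42.0), FLRT3 (37.9) and CXCR4 (34.3) lay near the median of all probe sets (34.8). Their differences therefore rest on a dim baseline.

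The lowest genes in both arrays were genes of long genomic span (84.8 to 603 kb for the 12 lowest). MAML2, a Notch coactivator spanning 367 kb, had an intensity of 318 in the untreated array, 41.8 in B1 and 58.9 in B2, a log2 difference of -2.68 (SE 0.31). TMEM117, a membrane protein gene of 603 kb, differed by -2.21 and -2.28. The log2 differences were -2.44 and -2.78 for NHS, an actin regulator, and -1.86 and -2.30 for THRB, the thyroid hormone receptor beta. They were -1.64 and -2.50 for the transcription factor NFIA and -2.20 and -1.80 for ZNRF3, a ubiquitin ligase that dampens Wnt signalling. RAPGEF5, an activator of Ras-related GTPases, differed by -2.53 and -2.19. The ephrin EFNA5 (-1.92 and -2.65), the zinc-sensing receptor GPR39 (-1.99 and -2.57), KLHL29 (-1.88 and -2.76) and the lipid phosphatase PLPP3 (-1.77 and -2.24) were also among the 12. For RAPGEF5 and KLHL29, 2 of 4 probe sets were lower in both arrays, for NFIA 4 of 7, and for EFNA5 3 of 4. Over all probe sets the mean log2 difference was nearer 0 for KLHL29 (-0.69), RAPGEF5 (-0.95), NFIA (-1.03), GPR39 (-1.11), EFNA5 (-1.41), THRB (-1.48), PLPP3 (-1.50), MAML2 (-1.63) and NHS (-1.97). The remaining gene of the 12, SRGAP1, differed by -1.67 and -2.51, and by -1.13 on average over all its probe sets.

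**Figure D1:**
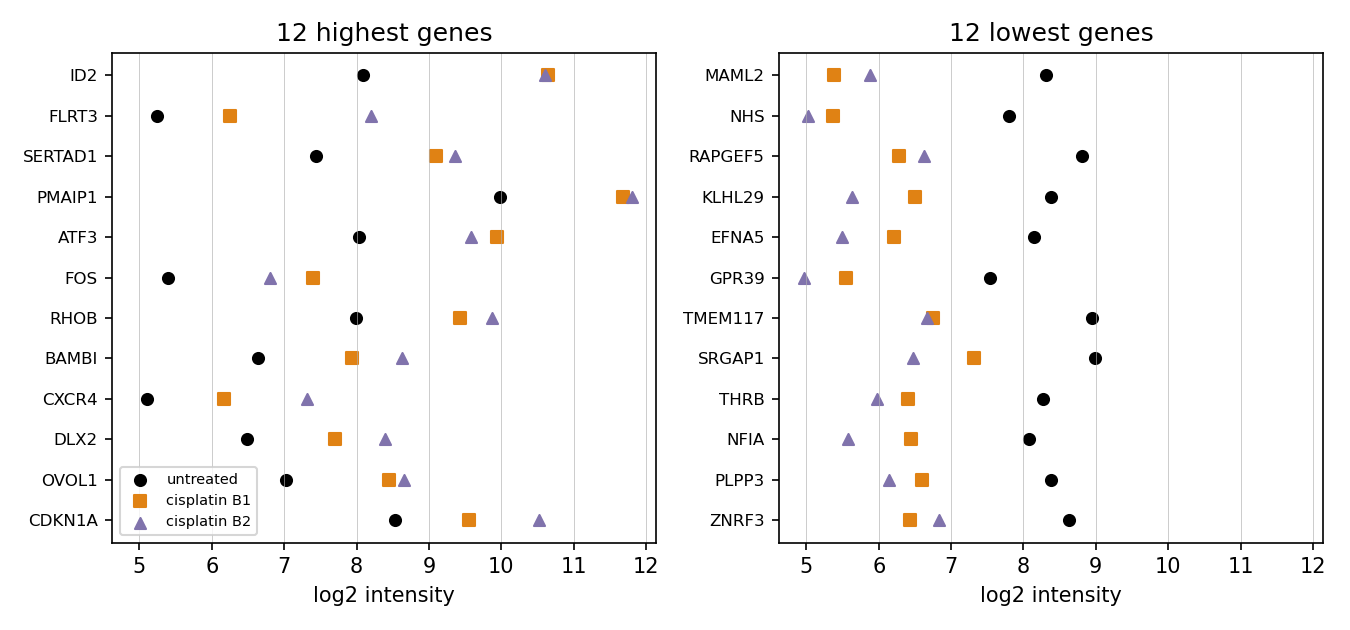
Log2 intensity (x axis) of the 12 highest and 12 lowest genes (y axis) under the 2-array size rule, with 1 point per array (black circle, untreated; orange square, B1; purple triangle, B2). Both cisplatin points lie on the same side of the untreated point for all 24 genes, and FLRT3 shows a wide gap between B1 and B2 (1.01 and 2.96 above untreated).

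No gene passed the limma test (0 of 19775 at an adjusted p of 0.05, smallest adjusted p = 0.97), while 565 genes had an unadjusted p under 0.05, 151 higher and 414 lower. Without any effect a share of 0.05 of the genes would be expected under that unadjusted p, and the 565 were a smaller share of the 19775. The same fit recovered 0% of simulated changes as large as 4 on the log2 scale, so the count of 0 was not informative about the size of the response. By the size rule, 28 genes were higher and 134 lower in both arrays by at least 2-fold. With the mean of each gene's probe sets in place of the brightest, these counts were 22 and 38. On that mean, which includes the brightest probe set, 133 of the 134 lower genes were still lower in both arrays. With B1 alone the counts were 47 and 299, and with B2 alone 591 and 890.

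Both differences share the untreated array, so part of their agreement is expected without any effect. Simulated unchanged arrays gave 72.9 higher and 73.9 lower genes with the moderated spread, and 214 of each with every gene's own spread, means of 100 simulations. The number of higher genes lay below these values, and the number of lower genes lay between them. Both spreads rest on the difference between B1 and B2 (SD 0.56), which was larger than that between B1 and untreated (SD 0.33). The simulated counts, and the simulated covariances below, therefore cannot settle what to expect without an effect. Independent lists would share 1.40 higher and 13.5 lower genes. The correlation of the B1 and B2 differences across genes was 0.39 (0.50 simulated), and their covariance was 0.0778 (0.0746 simulated with the moderated spread and 0.157 with each gene's own). Genes are not independent replicates.

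**Figure D2:**
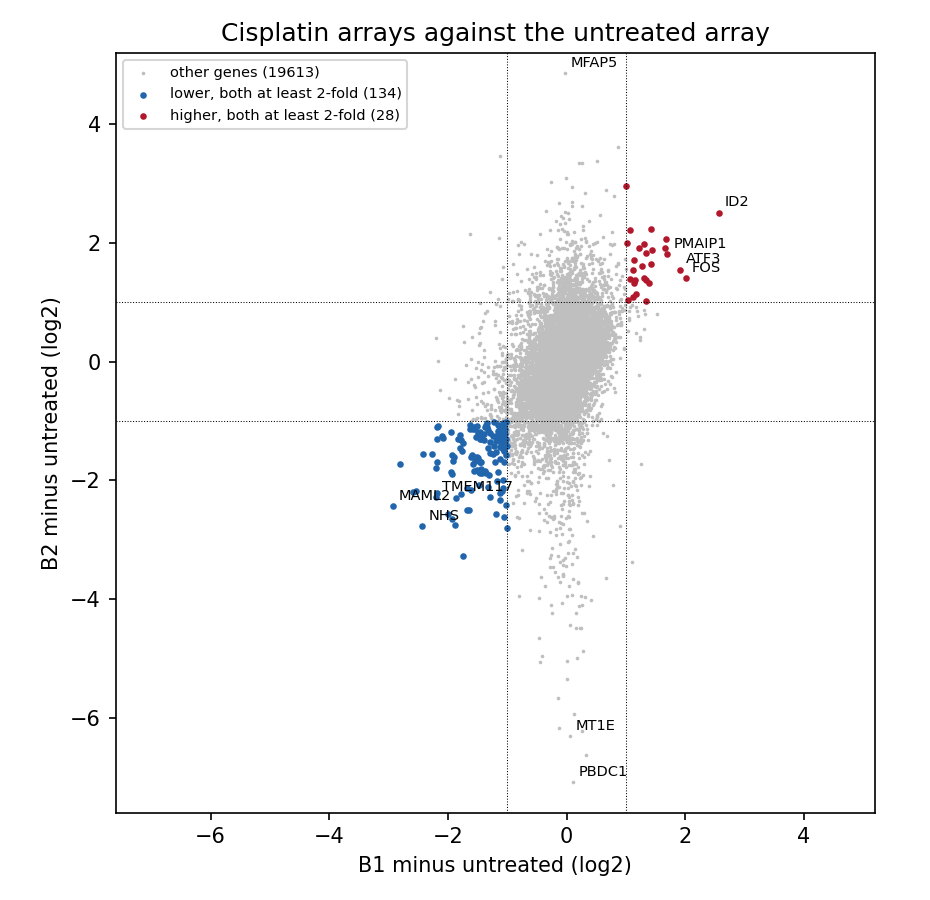
Log2 difference from the untreated array in B1 (x axis) and B2 (y axis), 1 point per gene, with dotted lines at 2-fold. The 28 genes higher in both arrays are red and the 134 lower ones blue, and the vertical spread (SD 0.60) exceeds the horizontal one (SD 0.33).

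Genomic span was examined after the lower genes had been seen. The 134 lower genes had a median span of 244 kb (133 with a span), the 28 higher genes 5.77 kb, and all genes 24.7 kb. Of the lower genes 93.2% spanned over 100 kb, against 16.9% of all genes, and 0 of the 28 higher genes did. Among 10203 genes with a mean log2 value of at least 6, the longest 10% had a median log2 difference of -0.53 in B1 and -0.43 in B2, and the shortest 10% 0.08 and 0.15. Of the longest 10%, 72.6% of genes were lower in both arrays, against 14.7% in the shortest. Spearman's rank correlation between span and log2 difference across genes was -0.56 in B1 and -0.31 in B2, and 0.02 between B2 and B1.

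**Figure D3:**
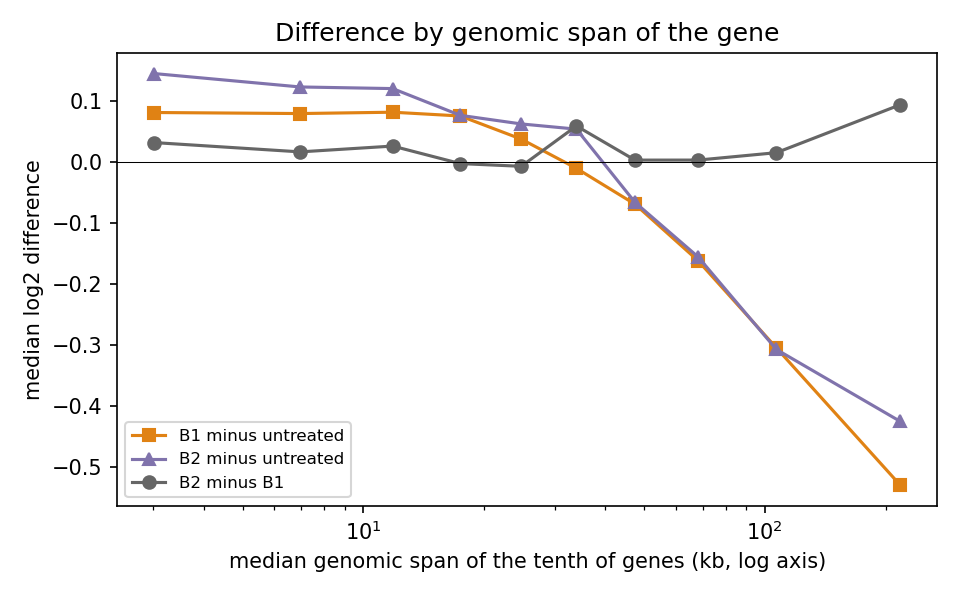
Median log2 difference (y axis) of genes in 10 groups of increasing genomic span (x axis, kb, log scale), for genes with a mean log2 value of at least 6. Orange squares are B1 minus untreated, purple triangles B2 minus untreated and grey circles B2 minus B1; in the longest group the first 2 reach -0.53 and -0.43, and B2 minus B1 reaches 0.09.

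Immediate early genes and short-lived regulatory transcripts, 2 of the 29 lists, were shifted upwards. Of 25 measured immediate early genes, 18 were higher and 3 lower in both arrays, with a median log2 difference of 0.47 in B1 and 0.55 in B2. JUN differed by 1.16 and 1.13, IER2 by 0.97 and 1.14, and FOSB by 0.90 and 0.94, whereas MYC differed by 0.04 and 0.55. Of 26 short-lived transcripts, 20 were higher and 0 lower in both arrays, with medians of 0.32 and 0.57, and TOB1, an antiproliferative factor, was higher by 1.30 and 1.40. The camera adjusted p was 2.9e-06 for each, and adjusted p = 0.90 with an estimated correlation. An estimated correlation rests here on the 1 residual degree of freedom, from the cisplatin pair, and none of the 29 lists was called with it. That setting could not tell a shifted list from an unshifted one, here or for the lists below. Camera at a preset correlation sets a list's genes against the other genes, so its adjusted p treats genes, not cultures, as replicates. The immediate early and short-lived lists share 5 genes. SERTAD1, ID2 and TOB1 passed the limma test when adjusted over the list alone (3 of 26), against 0 over all genes tested, and 0 of 25 immediate early genes passed either way. Each list's median lay at the 100th percentile of random lists in B1 and in B2.

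Heat shock and cholesterol synthesis genes were also shifted upwards by camera, more narrowly. Of 15 heat shock genes 11 were higher and 1 lower in both arrays, with medians of 0.14 in B1 and 0.21 in B2 (adjusted p = 0.042; adjusted p = 0.90 with an estimated correlation, and 0.065 by rank-based camera, where the list was not called). The co-chaperones DNAJB4 (1.098 and 0.947), DNAJB1 (0.83 and 1.47) and BAG3 (0.49 and 0.63) and the inducible HSPA6 (0.38 and 0.76) had the largest t values. Of 17 cholesterol synthesis genes 11 were higher and 0 lower in both arrays, with medians of 0.06 in B1 and 0.31 in B2, so that most of the shift was in B2 (adjusted p = 0.047; adjusted p = 0.90 with an estimated correlation), among them INSIG1 (0.67 and 0.40), IDI1 (0.49 and 0.32), MSMO1 (0.36 and 0.99) and HMGCS1 (0.26 and 1.11). No member of either passed, over all genes or adjusted over the list alone. Over all probe sets the mean log2 difference was 0.35 for HSPA6 and 0.23 for IDI1.

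Genes of the response to DNA damage did not move as one group. The p53 target list was not called (adjusted p = 0.47). Of its 27 measured members 12 were higher and 8 lower in both arrays, 2 of them (PMAIP1 and CDKN1A) past the size rule. GADD45A, a growth arrest gene, differed by 0.64 and 1.35, whereas ZMAT3 differed by -0.43 and -0.47 and MDM2, the ubiquitin ligase that degrades p53, by -0.18 and -1.12. GDF15 differed by 0.29 and 0.75. Nucleotide excision repair genes had medians of 0.00 and 0.05 (20 genes, adjusted p = 0.91), with UVSSA at -0.44 and -1.08, ERCC6 at -0.29 and -0.95, XAB2 at 0.29 and 0.47, ERCC2 at 0.34 and 0.17, ERCC1 at -0.05 and 0.49, and XPC at 0.15 and -0.57. Apoptosis effectors were not called (22 genes, 6 higher and 9 lower in both arrays, adjusted p = 0.47). APAF1, the apoptosome scaffold, was at -1.01 and -0.86 and CFLAR at -0.38 and -1.05, against 0.26 and 0.68 for BIK and 0.32 and 0.47 for BCL2. Several of these values rest on the brightest probe set: over all probe sets the mean log2 difference was -0.01 for CFLAR (6 of 14 probe sets lower in both arrays), -0.21 for MDM2 (4 of 10), -0.23 for UVSSA (2 of 4), -0.26 for ZMAT3, 0.30 for GDF15 and -0.41 for APAF1 and for BCL2, which changed sign.

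The Fanconi and homologous recombination list was shifted downwards (22 genes, 11 lower and 5 higher in both arrays, adjusted p = 0.047; adjusted p = 0.90 with an estimated correlation), with BARD1 (-0.63 and -0.56), BRIP1 (-0.60 and -1.16), BLM (-0.38 and -0.45) and FANCC (-0.30 and -0.59, but -0.14 on average over its 3 probe sets). The G2/M and mitosis list was shifted downwards too (30 genes, 13 lower and 2 higher in both arrays, adjusted p = 0.042; adjusted p = 0.90 with an estimated correlation), with BUB1B (-0.69 and -0.54), TTK (-0.49 and -0.58), KIF11 (-0.55 and -0.49) and CENPE (-0.72 and -0.45). Its median was -0.22 in B1 and 0.01 in B2, at percentiles 0 and 64.51 of random lists. The Fanconi median lay at percentiles 11.02 in B1 and 20.2 in B2. With the difference averaged over both arrays the percentiles were 35.86 (G2/M) and 13.71 (Fanconi), so random lists of matched expression often had medians as low. On that average the other called lists lay further out, among them heat shock (99.43), cholesterol synthesis (99.81) and metallothioneins (0). No member of either list passed, over all genes or adjusted over the list alone. Above a mean log2 value of 6 neither list was called (adjusted p = 0.19 and 0.26), and with the span trend removed, an alternative chosen after seeing the data, the Fanconi list was not (adjusted p = 0.11). DNA replication genes were not called (32 genes, adjusted p = 0.76), although CDC6 (0.68 and 0.76), E2F1 (0.53 and 0.62), CCNE1 (0.84 and 1.62, but 0.60 on average over its 2 probe sets) and GINS4 (0.34 and 0.75) were higher in both arrays. Replication-dependent histone genes had medians of 0.09 and 0.81 (9 genes, adjusted p = 0.092), with H2BC21 at 0.77 and 1.97.

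The list of metallothioneins and metal handling was called downwards (10 genes, 4 lower and 0 higher in both arrays, adjusted p = 0.042; adjusted p = 0.90 with an estimated correlation), with a median of 0.04 in B1 and -1.99 in B2, and above a mean log2 value of 6 it was not called (adjusted p = 0.14). MT1F differed by -0.15 and -3.27, MT1X by -0.05 and -2.35, and MT2A by -0.03 and -1.72. MT1M was dim, with an intensity of 5.74 in B2. Platinum transport genes were not called (12 genes, adjusted p = 0.33), with the copper transporter genes SLC31A1 at -0.02 and 0.23, ATP7B at -0.04 in each array, SLC31A2 at -0.08 and 1.07 and ATP7A at -0.12 and -1.95, and the drug exporter gene ABCG2 at -0.26 and -1.49.

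Several uncalled lists had different medians in B1 and B2. The medians were 0.00 and 0.56 for the integrated stress response (24 genes, adjusted p = 0.18; DDIT3 at 0.56 and 1.75), 0.07 and 0.26 for the unfolded protein response (16 genes, adjusted p = 0.18; DNAJB9 at 0.88 and 0.85), and 0.02 and -0.28 for NRF2 and glutathione genes (23 genes, adjusted p = 0.092; ABCC1 at -0.99 and -0.67). They were 0.02 and -0.41 for NF-kB and cytokine genes (21 genes, adjusted p = 0.18), where CXCL1 was at -1.04 and -1.14. Squamous differentiation genes had medians of 0.05 and 0.53 (24 genes, adjusted p = 0.47; KRT5, a basal keratin, at 0.14 and 1.80), epithelial and mesenchymal genes -0.01 and 0.34 (19 genes, adjusted p = 0.61; GRHL2 at -1.58 and -0.96), and interferon response genes 0.18 and -0.18 (23 genes, adjusted p = 0.91). MAP kinase feedback genes (16 genes, adjusted p = 0.996) had medians of -0.14 and 0.34, and TGF-beta and BMP targets (16 genes, adjusted p = 0.47; 1 of 16, ID2, passed adjusted over the list alone) -0.21 and 0.41.

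Other uncalled lists had medians nearer 0. These were 0.01 and 0.10 for ribosomal proteins (22 genes, adjusted p = 0.68), 0.02 and 0.02 for oxidative phosphorylation (23 genes, adjusted p = 0.99), 0.00 and 0.03 for ribosome biogenesis (20 genes, adjusted p = 0.91) and -0.06 and -0.04 for hypoxia and glycolysis (23 genes, adjusted p = 0.74). Members of the last went both ways: ANKRD37 was at 0.98 and 1.22 and EGLN3 at 0.42 and 0.67, against -0.52 and -0.88 for HK2 (-0.39 on average over its 3 probe sets) and -0.38 and -0.68 for SLC2A1. Of the reference genes, ACTB was at -0.10 in each array, GAPDH at -0.02 and -0.19, TBP at 0.13 and 0.12, HPRT1 at -0.07 and -0.15, B2M at 0.06 and 0.04, and GUSB at 0.23 and 0.43. PPIA was at -0.01 and 0.06 and changed the sign of its mean with median centring. Among the reference genes, the mean over all probe sets differed most from the brightest for B2M (0.31) and PPIA (0.20). Markers of other cell types had median differences of 0.05 and 0.08 for fibroblasts (13 genes, adjusted p = 0.47; THY1 at 0.05 and 1.28, COL5A1 at 0.57 and 1.05), 0.14 and 0.11 for leukocytes (12 genes, adjusted p = 0.53) and 0.18 and 0.09 for endothelium (10 genes, adjusted p = 0.63). The median, mean and camera direction differed in sign for DNA replication, hypoxia and glycolysis, interferon response, ribosome biogenesis and oxidative phosphorylation.

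**Figure D4:**
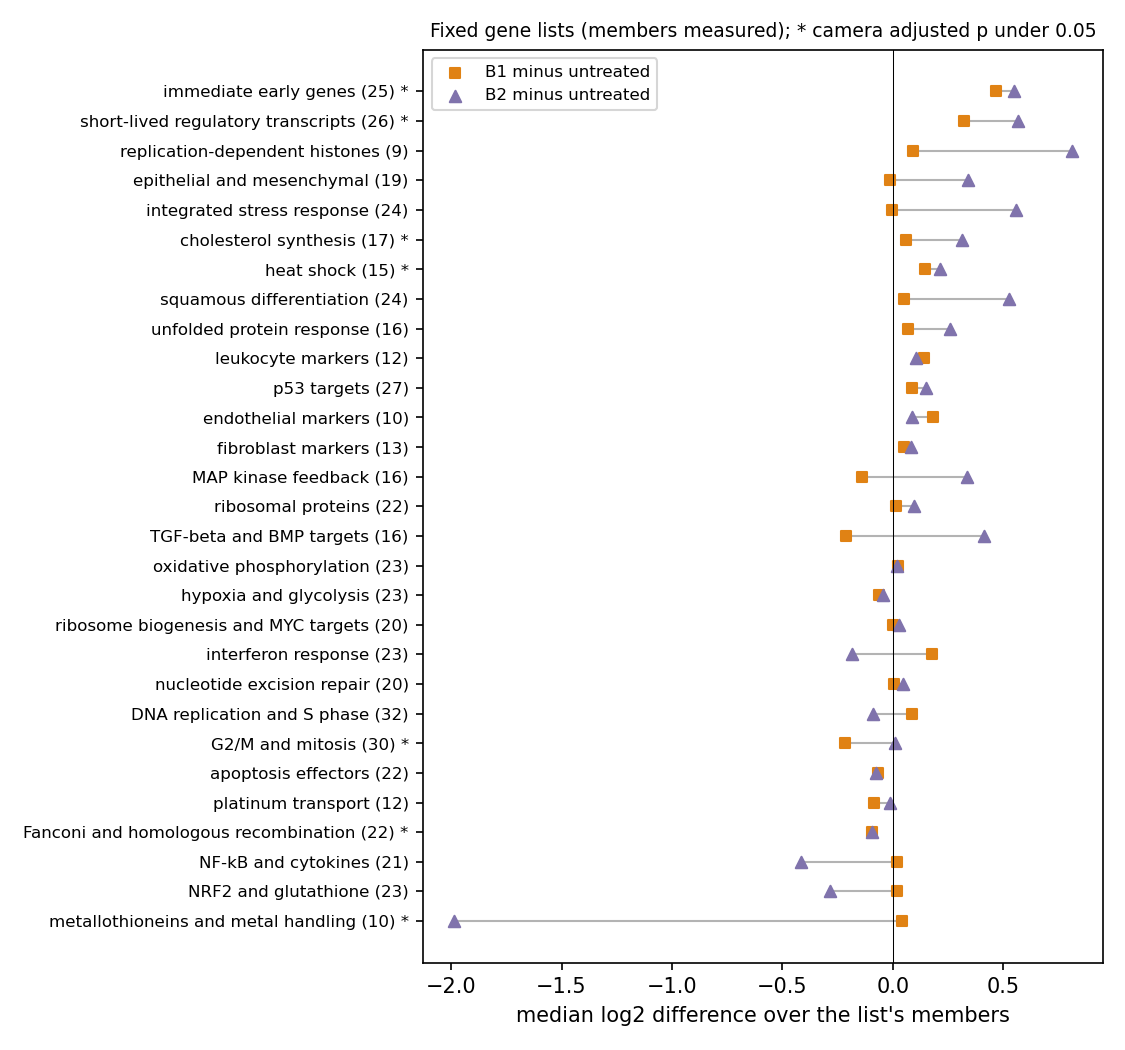
Median log2 difference over the measured members of each of the 29 fixed lists (x axis) in B1 (orange squares) and B2 (purple triangles), with the number of members after each name and an asterisk where camera's adjusted p was under 0.05. Immediate early genes (0.47 and 0.55) and short-lived transcripts (0.32 and 0.57) lie to the right in both arrays, and metallothioneins lie at 0.04 in B1 and -1.99 in B2.

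The cisplatin arrays differed from each other more than B1 differed from the untreated array. Across genes the SD of the log2 difference was 0.56 between B2 and B1, 0.33 between B1 and untreated, and 0.60 between B2 and untreated, and the correlations of log2 levels were 0.974, 0.991 and 0.972. At least 2-fold differences from untreated numbered 47 higher and 299 lower genes in B1, and 591 and 890 in B2. Set alone against the other 2 arrays by the same size rule, B2 had 415 higher and 476 lower genes, B1 had 3 higher and 76 lower, and the untreated array had 134 higher and 28 lower. In 23 genes B2 lay over 16-fold from both other arrays, 22 of them lower. These genes were chosen after their values were seen: PBDC1 had intensities of 796 (untreated), 855 (B1) and 5.87 (B2), TRMT11, a tRNA methyltransferase subunit, 350, 353 and 8.63, and the metallothionein MT1E 14919, 15441 and 188, while the matrix protein gene MFAP5 had 26.4, 25.8 and 767. The 3' to 5' signal ratios differed by at most 0.08 on the log2 scale from untreated for ACTB and GAPDH control probe sets.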

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

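Of the tests below, that of a stronger response was chosen after the result was seen, and those of probe sets and of neighbouring genes were written before theirs. Among 13522 probe sets with no single gene name, used only where every probe set was tested on its own, 63 were lower and 46 higher by 2-fold or more in both cisplatin arrays. These are 0.47% and 0.34%, against 0.72% and 0.20% of the 41091 probe sets with 1 gene name.

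B2 stood apart from both other arrays, with 891 genes past the size rule against 79 for B1 and 162 for the untreated array, and 23 genes over 16-fold away. Noise of single probe sets is argued against by the 353 other probe sets of these genes with a mean log2 value of at least 6 (238 of the 891 genes), of which 97.2% lay on the same side. A stronger response to the same drug stays open: the shift in B2 was 0.80 times that in B1 for the longest 10% of genes (95% bootstrap interval over genes 0.72 to 0.89), but 1.18 times for immediate early genes and 1.74 times for short-lived transcripts. Cells of another genetic make-up, such as a diverged stock or another line, are a candidate explanation, because medians over 187 blocks of 50 neighbouring genes spread 2.53 times as widely for B2 as in random gene order, and 2.54 times with span removed, against 1.79 and 1.21 times for B1 against untreated (permutation p = 0.001 for each of the 4 values, the smallest 1000 orders can give). Random gene order removes likeness of neighbouring genes from any source, so the wider spread does not by itself point to a genetic difference. A different culture or batch for B2, or a technical trend along the genome, stays open, and the identity of the cells was not tested.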

How the results depend on the processing

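The alternative with span removed was chosen after seeing the data. No gene passed limma's adjusted p of 0.05 under the 11 alternatives run. Of them, 9 had a count of their own at an unadjusted p under 0.05. The lowest was 259 genes and the highest 2165 probe sets, where every probe set was tested on its own. Each count was under the share of 0.05 expected without any effect. Without 1 cisplatin array no residual degrees of freedom remained. The size rule gave 189 higher and 524 lower genes at 1.5-fold, 4 and 24 at 3-fold, and 38 lower with the mean of each gene's probe sets. The cause of that smaller count was not tested. The direction was kept in 133 of the 134 lower genes, but this was partly fixed in advance. The mean includes the probe set by which they were chosen, and 13 of them have only 1 probe set. On the same mean, the rank correlation between span and difference was -0.55 in B1 and -0.30 in B2. From each cisplatin array alone the size rule gave 47 (B1) to 591 (B2) higher and 299 (B1) to 890 (B2) lower genes. Of the 29 lists, 7 were called. With an estimated correlation 0 were called, which is not informative because that estimate rests on 1 residual degree of freedom. With a preset of 0.05, 2 were called (immediate early genes and short-lived transcripts), and by rank-based camera 6 (not heat shock). Above a mean log2 value of 6, 5 were called, and with span removed 6. For these other settings the cause was not tested. The integrated stress response was called above a mean log2 value of 6 (adjusted p = 0.024). The SD between the cisplatin arrays was 0.67 above that level, where dim genes are left out. With the mean of all probe sets BCL2 turned to -0.41 and RPL14 to 0.0055, and with median centring PPIA turned to -0.012; the other 143 and 144 of 145 named genes kept their direction. No paired analysis was possible because the untreated group holds 1 array. Signal over background was not judged, as no detection calls were used.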

Other observations

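Further genes apart in B2 are given here, chosen after their values were seen. KRT14, a basal keratin, had intensities of 278 (untreated), 276 (B1) and 2372 (B2), vimentin (VIM) 78.8, 97.47 and 565, and EFEMP1, a matrix protein, 127, 147 and 1296. Carbonic anhydrase CA2 was at 913, 1151 and 9.23, and the receptor GPRC5A at 1564, 1413 and 30.9. Markers of fibroblasts, leukocytes and endothelium had medians of 0.08, -0.03 and 0.04 in B2 minus the mean of the other arrays.

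One hypothesis for the lower genes, reduced transcription of long genes with the treatment, is not decided by these arrays; all tests in this paragraph were chosen after the result was seen. The trend itself, a rank correlation between span and difference across genes of -0.307 in B2 and -0.56 in B1, prompted the hypothesis and does not test it. Bias from intensity or normalization is argued against, since the median of the longest 10% differed from that of shorter genes at the same mean level by -0.54 in B2 and -0.61 in B1. RNA degradation was also tested and left open: the 3' to 5' log2 ratio of control probe sets differed from untreated by at most 0.08. Something particular to the single untreated array cannot be told apart from the treatment, because the contrast without it (B2 minus B1, rank correlation 0.0174) would be flat under either.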
